A study of Mus musculus with 4 samples.

How the data were processed

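The files hold counts of reads per gene for 4 libraries of sorted mouse kidney cells, 2 control and 2 Brg1-cKO. Per the labels' protocols, total RNA was prepared from 3000 cells per sample, mRNA was purified with magnetic beads, strand-specific libraries were made by random priming with a low-input kit, and single-end reads of 75 bp were sequenced. The deposited counts are whole numbers, 1 per gene and library, with closing lines for reads given to no gene. Per the submitters' processing notes, the mm10 build, TopHat and DESeq2 were used, without versions. The counting tool, its strand setting and the annotation were not given in the sources used here. A counting that ignored strand would add antisense reads to a gene, and reads of overlapping genes go to neither.

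Of 52636 gene identifiers, 52403 were matched to a symbol and 52489 to a position in GENCODE mouse release M21, whose coordinates are on the same build. Reads given to no gene (outside genes, ambiguous, unaligned or aligned to several places) made up 32.4% and 31.8% of all reads in the controls and 65.5% and 72.1% in the Brg1-cKO libraries. They were left out of library sizes and tests. Reads called outside genes aligned uniquely but matched no counted feature. The features counted were not given, so these reads can lie in introns, or antisense to exons if strand was used. Mitochondrial and ribosomal protein shares were taken over total gene counts, the share outside genes over uniquely aligned reads and the unaligned share over all reads, and with such totals the 95% Wilson intervals are narrow. The widest runs from 57.2% to 57.3%, for the reads outside genes in Brg1-cKO replicate 2. A count of 0 allows up to 3 counts, or 0.0789 to 0.275 CPM depending on the library. The reads carry no molecular identifiers, so these intervals and floors cover counting error only.

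Groups came from the label that names each sample's condition. The comparison was fitted with edgeR 4.0.16 in R 4.3.3 on the deposited counts with the group as its only term. It used TMM normalization, the default expression filter (minimum count 10), robust dispersions and the quasi-likelihood F test, with Benjamini-Hochberg adjustment at 0.05. The filter left 18172 genes. Values in CPM use library sizes scaled by TMM and are given as mean ± SD over 2 libraries. Standard errors are the log2 fold change divided by the root of the F statistic. Where both libraries of a group had 0 counts, the fold change was bounded with 3 counts over the group.

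Before the data were examined, 28 gene lists were fixed, as were the test design, most alternatives and the rule for named genes. The rule names Smarca4 and Smarca2, 14 kidney development genes whatever their p, and genes past the adjusted threshold. If fewer than 10 genes pass, it names the 5 higher and 5 lower genes with the smallest p, no overlap between groups, at least 10 CPM in the higher group and no predicted or clone name. Some genes that the rule names are not reported here. List members past the threshold over their list alone were named in addition, after their values were seen. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. The fry test asks whether a list's genes move 1 way on balance and does not compare them with other genes. The nephron progenitor, podocyte, early nephron and Wnt lists share some genes.

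The functions were tested on simulated data before use, drawn for the real genes with 200 of them changed by known folds. The changed genes were taken from those at 10 CPM or more in control, and dispersions followed their estimated trend with expression. With the control dispersion in both groups (17459 genes tested), edgeR called 49 of 50 genes changed by 2-fold, and 50 of 50 at each of 4-fold, 8-fold and 16-fold, with 10 false calls among 209. With the dispersion measured in each group (17184 genes tested), it made 0 calls, and 11.6% of unchanged genes had an unadjusted p under 0.05. In that simulation, of 500 random lists of 20 unchanged genes, 4.2% had a camera p under 0.05 with the preset correlation, 0% with an estimated one and 28.4% with fry. In 3.2% of them at least 1 member passed adjusted over the list alone. Genes were drawn independently, so these rates do not cover lists whose members move together.

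The alternatives were DESeq2 1.42.0, other scalings (RLE, total counts), other filters on low counts, a replicate block, each library left out in turn, the likelihood ratio test, limma-voom (limma 3.58.1), a test against a fold of 1.5, an adjusted p of 0.01, and library sizes without mitochondrial, ribosomal protein and hemoglobin genes. Added after seeing the data were edgeR without robust dispersions, limma-voom with a variance per group, a filter of 10 CPM in 2 libraries, and counts thinned to the smallest library. Other splits of the libraries were not fitted, and with groups of 2 an exact permutation p cannot go below 0.333.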

Results

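RNA was sequenced from mouse kidney cells purified by fluorescence-activated cell sorting, in a control group and in a group labelled Brg1-cKO, by usual usage a conditional knockout of Brg1. Brg1 is the protein of Smarca4, the ATPase of SWI/SNF complexes, which move nucleosomes at promoters and enhancers. Each group had 2 libraries, each made from 3000 cells. The sorting marker, the age of the kidneys and the deleting allele were not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate animals. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. Camera p-values with a preset correlation rest on the spread across genes, so they can be small with 2 libraries per group. They do not measure the spread between animals.

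The counts on genes were 35411905 and 37999342 in the control libraries and 14645665 and 10922272 in the Brg1-cKO libraries. Reads that aligned uniquely but matched no counted feature made up 53.4% ± 5.47 (SD, n = 2) of uniquely aligned reads in Brg1-cKO. In control they made up 15.9% ± 0.775 (SD, n = 2). They are called outside genes here but can lie in introns. Reads that did not align made up 23.4% ± 2.92 of all reads in Brg1-cKO and 6.50% ± 0.262 in control. With the gene counts of every library thinned to the smallest total, 17059 ± 1385 genes were detected in Brg1-cKO and 24234 ± 86.3 in control. Genes at 10 CPM or more numbered 10236 ± 282 in Brg1-cKO and 10067 ± 12.02 in control, so the lower detection concerned scarce transcripts. On each of these measures except the last, both Brg1-cKO libraries lay on the same side of both controls. The smallest exact two-sided permutation p that 2 against 2 libraries allow is 0.333. Across the tested genes, log2 CPM correlated at r = 0.992 between the controls, 0.826 between the Brg1-cKO libraries and 0.872 to 0.878 across groups. Genes are not independent replicates, and these values only describe the libraries. The controls still differed by more than sampling noise (chi-square per gene 9.68), as did the Brg1-cKO pair (127), so no library was a copy of another.

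**Figure D1:**
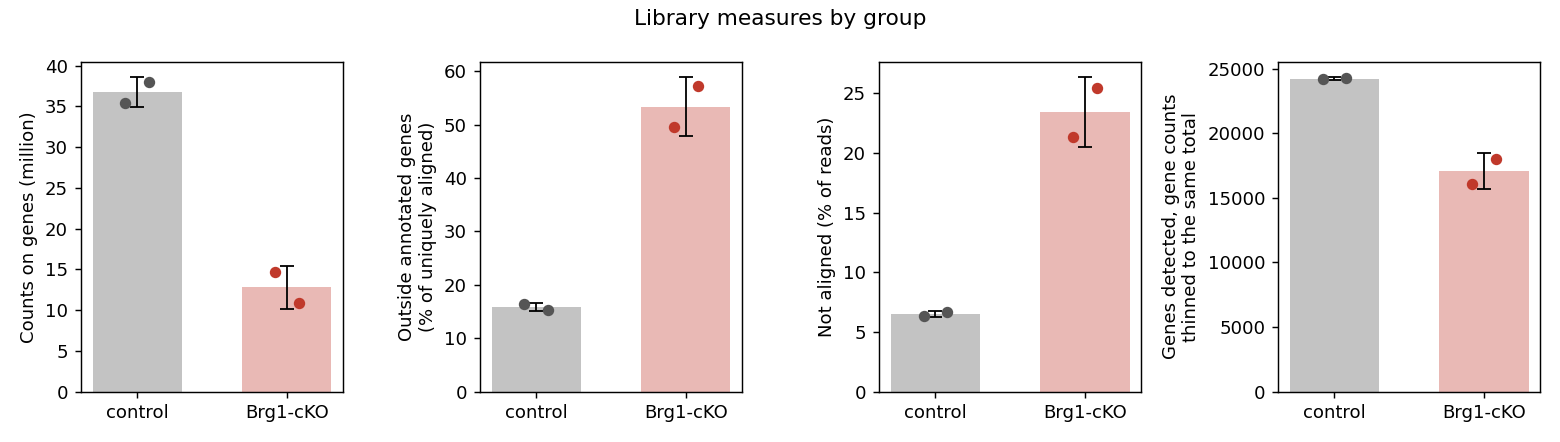
Library measures in control and Brg1-cKO, with bars for group means, whiskers for the SD and 1 point per library (n = 2). The y axes give counts on genes (M), reads that matched no counted feature as a percent of uniquely aligned reads, and unaligned reads as a percent of all reads. The axis names the second measure outside annotated genes, but it can include introns. The last y axis gives genes detected after thinning gene counts to the smallest total, which was 24234 in control and 17059 in Brg1-cKO.

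The comparison of Brg1-cKO with control asks how gene expression in the sorted kidney cells differs where Brg1 was targeted. Xist was higher and the Y-linked Ddx3y lower in both Brg1-cKO libraries than in both controls. The sex of the cells may thus differ between the groups, and no fit separated it from genotype. Smarca4 was at 760 and 691 CPM in the Brg1-cKO libraries and at 898 and 937 CPM in the controls. Podocyte genes, which build the glomerular filter, stood higher in Brg1-cKO, with all 15 tested members above control and a median log2 fold change of 1.85. Markers of the early nephron were also mostly higher, in 17 of 21. Ureteric bud genes were lower in 14 of 16, stromal genes in 17 of 22, endothelial genes in 14 of 16 and immune genes in 14 of 15. Six2, the transcription factor that keeps nephron progenitors undifferentiated, was at 234 and 126 CPM in Brg1-cKO against 239.6 ± 3.27 CPM in control (SD, n = 2), and its log2 fold change of -0.41 (SE 0.34) passed no test that used all 4 libraries.

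The Smarca4 difference was a log2 fold change of -0.34 (SE 0.09). Taken alone, as the targeted gene, it had a model-based p = 0.0193 in edgeR's quasi-likelihood test, where an exact test of 2 against 2 libraries cannot go below 0.333. Over all genes the adjusted p was 0.167. Without control replicate 1 the single-gene p was 0.168, and without control replicate 2 it was 0.255. Smarca4 (ENSMUSG00000032187) lies on chromosome 9 from 21616169 to 21704230 on the plus strand (mm10, with GENCODE annotation). The counts cover the whole gene and can include exons outside a deleted part, so they check the labels only in part. Smarca2, which encodes the alternative SWI/SNF ATPase, was at 97.7 ± 2.03 CPM in Brg1-cKO and 82.6 ± 0.990 CPM in control, with a log2 fold change of 0.24 (SE 0.18, edgeR adjusted p = 0.594).

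Of 18172 genes tested, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, where the smallest adjusted p was 0.166. At an unadjusted p under 0.05 there were 3328 genes, of which 988 were higher and 2340 lower in Brg1-cKO. Genes at 0 counts in both Brg1-cKO libraries, 1527 of those tested against 52 in both controls, can count among the lower ones. In the simulation with measured dispersions, 11.6% of unchanged genes had an unadjusted p under 0.05 in the same test. With a filter of 10 CPM in 2 libraries the balance turned, to 827 higher and 595 lower, as it did with the replicate block (611 and 526) and with DESeq2 (2487 and 1860). It also turned without control replicate 1 (219 and 59) and without control replicate 2 (222 and 57). Other tools made calls, namely 2027 with DESeq2, 2471 with edgeR's likelihood ratio test, 327 with limma-voom and 134 with limma-voom and a variance per group. Leaving out a Brg1-cKO library left a single one that was assumed to vary like the controls, and then 12150 genes passed without replicate 1 and 13134 without replicate 2. Without control replicate 1 or 2, 18 and 13 genes passed. The biological coefficient of variation was 1.11 between the Brg1-cKO libraries and 0.173 between the controls. In counts simulated with each group's trend of dispersion with expression, the quasi-likelihood test called 0 of 50 genes changed by 2-fold. It likewise called 0 of 50 at 4-fold, 8-fold and 16-fold. The changed genes were all at 10 CPM or more in control. In the same simulation DESeq2 called 942 genes, of which 810 were unchanged, and the likelihood ratio test called 1104, of which 988 were unchanged. Without Brg1-cKO replicate 1 the simulated counts gave 11896 calls, of which 11702 were unchanged genes.

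With 0 genes past the threshold, the rule for named genes took the 5 higher and 5 lower genes with the smallest p. The higher ones included Enpep, Podxl, Igfbp7 and Dpp4. Enpep, which encodes glutamyl aminopeptidase, was at 395.9 ± 1.48 CPM in Brg1-cKO against 99.6 ± 3.88 CPM in control, a log2 fold change of 1.99 (SE 0.12). Podxl, the podocyte sialomucin podocalyxin, was at 1557 ± 280.1 against 280.4 ± 1.57 CPM, a log2 fold change of 2.47 (SE 0.16). The log2 fold change was 2.16 (SE 0.16) for Igfbp7, a secreted growth factor binding protein. It was 1.85 (SE 0.14) for Dpp4, a dipeptidyl peptidase of the cell surface. The lower genes were Col1a1, Egr1, Mest, Col3a1 and Col5a2. Col1a1 and Col3a1, the chains of fibrillar collagens, were at 476 ± 13.2 and 439.8 ± 20.8 CPM in Brg1-cKO against 1039 ± 11.4 and 938 ± 4.98 CPM in control, log2 fold changes of -1.13 (SE 0.08) and -1.09 (SE 0.09). Egr1, an immediate early transcription factor, was at 1056 ± 55.8 against 2126 ± 31.1 CPM, a log2 fold change of -1.01 (SE 0.07). Mest, an imprinted gene, had -0.98 (SE 0.07), and Col5a2, another fibrillar collagen, had -2.63 (SE 0.22). All 10 had an adjusted p of 0.166 over all genes in edgeR's quasi-likelihood test. Each of those named here passed over all genes with DESeq2, with the likelihood ratio test and with the replicate block, and each but Col5a2 with limma-voom (adjusted p = 0.0526 for Col5a2). These tools used the same counts from which the genes were picked, so their calls are no separate support. For Podxl the adjusted p was 8.58e-40 with DESeq2, 2.09e-19 with the likelihood ratio test, 4.87e-20 with the replicate block and 0.0400 with limma-voom. Enpep, Podxl, Igfbp7 and Egr1 also passed without either control library.

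On mm10, Enpep lies on chromosome 3 from 129269175 to 129332720, Podxl on chromosome 6 from 31519488 to 31563981, Igfbp7 on chromosome 5 from 77349240 to 77408041 and Dpp4 on chromosome 2 from 62330073 to 62412231. Col1a1 lies on chromosome 11 from 94936224 to 94953042, Egr1 on chromosome 18 from 34859823 to 34864984, Mest on chromosome 6 from 30723547 to 30748465, Col3a1 on chromosome 1 from 45311538 to 45349706 and Col5a2 on the same chromosome from 45374321 to 45503282. Six2 lies on chromosome 17 from 85684277 to 85688274, and Eya1 on chromosome 1 from 14168954 to 14310235. All are protein-coding genes in the annotation used here. Igfbp7, Mest, Dpp4 and Pax8 share exon sequence with their antisense neighbours Polr2b, Copg2, Gm13561 and Gm13415, and Smarca2 with an antisense noncoding gene. The strand setting of the counting was not given. If strand was ignored, reads in the shared parts go to neither gene, so it is not known which of them were counted. Of the genes given further on, Nphs1, Slc34a1, Lef1, Ccnd1, Meis1, Gfra1, Wnt7b, Fn1, Jun and Cdkn1c also overlap an antisense gene, and Meis1 and Ecm1 a gene on their own strand. Smarca4 and Col3a1 each overlap a predicted gene on their own strand (Gm27373 and Gm47302).

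**Figure D2:**
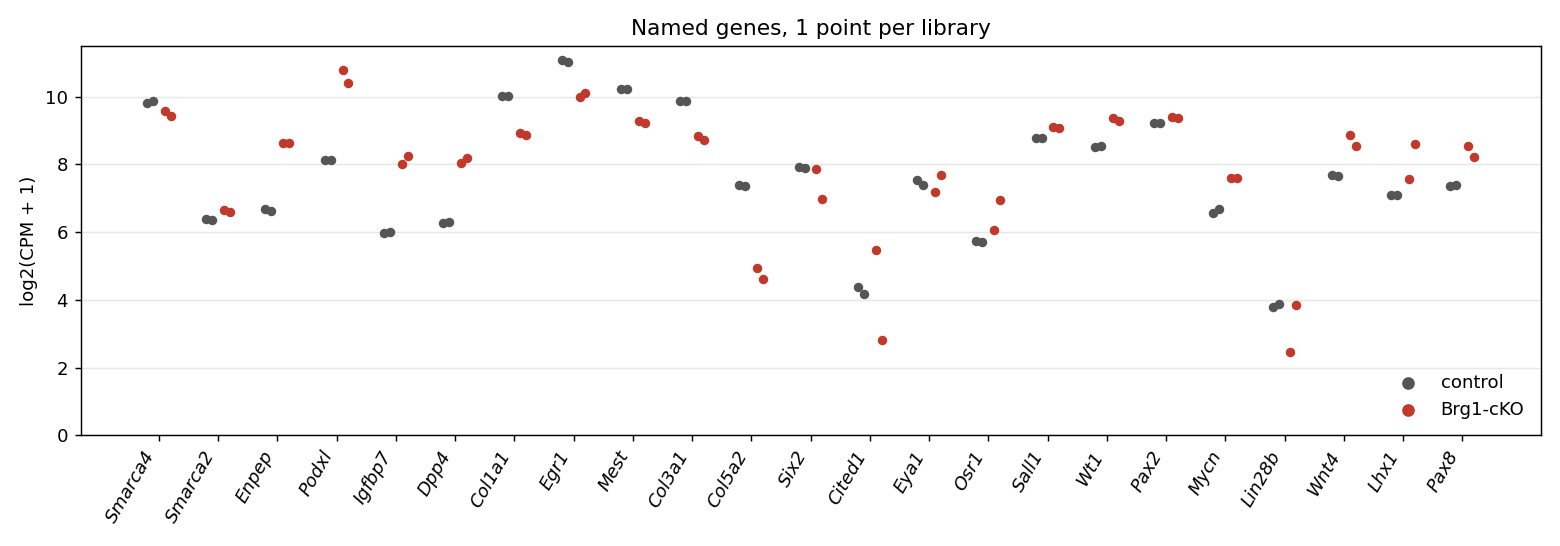
Expression of named genes, with 1 point per library (2 control, 2 Brg1-cKO) and log2(CPM + 1) on the y axis. The 2 Brg1-cKO points of Cited1 lie on opposite sides of the controls, while those of Podxl, at 1755 and 1359 CPM, lie above both controls at 279 and 281.5 CPM.

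The podocyte list was higher as a set (camera with a preset correlation, adjusted p = 1.0e-15). This call was lost with an estimated correlation (adjusted p = 0.339), while fry gave an adjusted p of 0.00472. In the simulation with measured dispersions, fry had an unadjusted p under 0.05 in 28.4% of lists of unchanged genes. Camera with an estimated correlation had this in 0% of them. Fry values here and for the lists that follow are thus weak support. Of the 15 podocyte members, 0 passed over all genes in edgeR's quasi-likelihood test, where 13 had an unadjusted p under 0.05. Adjusted over the list alone 13 passed, all higher. Podxl passed over all genes with the other tools named for it. Nphs1, which encodes nephrin of the slit diaphragm, was at 174.9 ± 32.6 CPM in Brg1-cKO against 21.9 ± 0.208 CPM in control, a log2 fold change of 2.99 (SE 0.23). Clic5 had a log2 fold change of 2.76 (SE 0.24). These examples, and those of the lists that follow, were chosen after their values were seen. Of the tubule list, 9 of 16 members were higher and 7 lower, and the set did not pass (camera adjusted p = 0.292). Slc12a1, Pou3f3 and Slc34a1 passed adjusted over the list alone, with log2 fold changes of 3.83 (SE 0.53), 1.30 (SE 0.19) and 3.59 (SE 0.59). Slc12a1 and Slc34a1 are transporters of the thick ascending limb and the proximal tubule.

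The early nephron list, of genes of the pretubular aggregate and renal vesicle, was higher as a set (camera adjusted p = 7.32e-05). It was not called with an estimated correlation (adjusted p = 0.411), and fry gave an adjusted p of 0.00472. Adjusted over the list alone, 5 of 21 members passed, namely Wnt4, Pax8, Jag1, Lef1 and Ccnd1. Wnt4, the signal that drives condensing progenitors into epithelium, was at 420.2 ± 70.6 CPM in Brg1-cKO against 204 ± 3.17 CPM in control, a log2 fold change of 1.04 (SE 0.16), and Pax8 had 1.02 (SE 0.16). Lhx1 had 1.08 (SE 0.38), and its adjusted p over the list alone was 0.146. The Wnt and beta-catenin target list was higher in 11 of 16 (camera adjusted p = 0.0340), with an adjusted p of 0.411 under an estimated correlation and 0.114 with fry. Its 4 members past the threshold over the list alone, Wnt4, Pax8, Lef1 and Ccnd1, are also in the early nephron list. Without Brg1-cKO replicate 2 its adjusted p was 0.143, and with the replicate block 0.0525. The Notch list did not pass (6 of 12 higher, camera adjusted p = 0.583), and Jag1, at a log2 fold change of 0.62 (SE 0.11), passed over the list alone.

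Nephron progenitor genes were mixed. As a set they were higher (19 of 25, median log2 fold change 0.25, camera adjusted p = 0.00860). The call was lost with an estimated correlation (adjusted p = 0.411), with fry (0.185), at 10 CPM in 2 libraries and without Brg1-cKO replicate 1. Wt1, a transcription factor of progenitors and podocytes, alone passed over the list alone, at 641 ± 30.3 CPM in Brg1-cKO against 369 ± 6.27 CPM in control (log2 fold change 0.80, SE 0.09). Eya1, the partner of Six2 named in the title of the series, was at 174 ± 42.9 against 176 ± 12.9 CPM, a log2 fold change of -0.01 (SE 0.23), and passed as lower without Brg1-cKO replicate 2 (-0.29, edgeR adjusted p = 0.00474) and as higher without replicate 1 (0.22, adjusted p = 0.0202). Cited1, a marker of uncommitted progenitors, was at 43.0 and 5.98 CPM in the Brg1-cKO libraries against 18.6 ± 1.86 CPM in control. Its log2 fold change was 0.40 (SE 1.03), 1.21 without Brg1-cKO replicate 2 (edgeR adjusted p = 6.45e-06) and -1.63 without replicate 1 (adjusted p = 6.48e-05), so the calls went opposite ways. Six2 in turn had -0.93 without Brg1-cKO replicate 1 (edgeR adjusted p = 1.44e-08, with the lone library assumed to vary like the controls) and -0.04 without replicate 2 (adjusted p = 0.607), so its level differed between the Brg1-cKO libraries as much as from control. Osr1 had a log2 fold change of 0.86 (SE 0.37), Sall1 0.30 (SE 0.09) and Pax2 0.17 (SE 0.08), none past the threshold over the list.

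In the Six-Eya-Dach-Pbx list, 7 of 18 members were higher and 11 lower (camera adjusted p = 0.988). Meis1, a homeobox gene of the renal stroma, passed over the list alone with a log2 fold change of -1.35 (SE 0.16). In the Myc, Lin28 and Igf2 list, 5 of 14 were higher (camera adjusted p = 0.988), and Mycn passed over the list alone, at 193 ± 0.583 CPM against 98.1 ± 4.91 CPM (log2 fold change 0.98, SE 0.15). Lin28b had -0.56 (SE 0.84), and 4.54 and 13.5 CPM in the Brg1-cKO libraries. The SWI/SNF subunit list was higher as a set (19 of 26, camera adjusted p = 0.0137), with Smarca4 itself lower and 0 members past the threshold over the list alone. It was not called with an estimated correlation (adjusted p = 0.411), with fry (0.206), at 10 CPM in 2 libraries or without Brg1-cKO replicate 1. Camera compares a list with the other tested genes, which here include 1527 at 0 counts in both Brg1-cKO libraries.

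**Figure D3:**
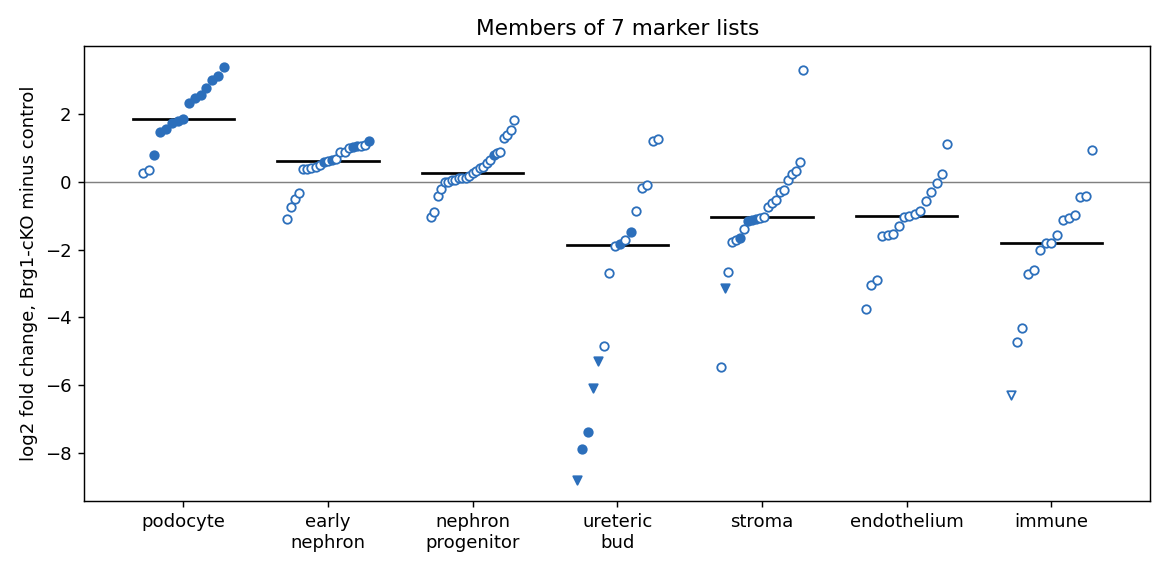
Log2 fold change (Brg1-cKO minus control, y axis) of each tested member of 7 marker lists, with a black line at each list's median. Filled symbols passed adjusted over the list alone, and triangles mark members at 0 counts in 1 group, drawn at the bound that 3 counts over the group allow. All 15 podocyte genes lie above 0 and 14 of 16 ureteric bud genes lie below.

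Ureteric bud genes, of the epithelium that forms the collecting system, were lower as a set (camera adjusted p = 5.43e-04, 0.414 with an estimated correlation, fry adjusted p = 0.0612). Over the list alone 7 of 16 passed, all lower, namely Calb1, Gfra1, Ret, Krt18, Wnt9b, Wnt7b and Slco4c1. Calb1, the calcium-binding protein calbindin, was at 52.9 ± 2.49 CPM in control and at 0 counts in both Brg1-cKO libraries, which puts its log2 fold change at -8.78 or below against a floor of 3 counts over the group. Ret, the receptor of the branching signal Gdnf, was at 21.6 ± 0.874 CPM in control and 0.0934 ± 0.132 CPM in Brg1-cKO. Gfra1, its co-receptor, had a log2 fold change of -1.50 (SE 0.22). The list's median was -1.87 with genes at 0 set to their bound. Fewer ureteric bud cells in the sort and lower expression within cells cannot be told apart here.

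Stromal genes were lower as a set (camera adjusted p = 0.00254, 0.411 with an estimated correlation, fry adjusted p = 0.00472). Over the list alone 5 of 22 passed, all lower, namely Col1a1, Col3a1, Ntn1, Ecm1 and Ren1. Ren1 was at 1.06 ± 0.229 CPM in control and at 0 counts in both Brg1-cKO libraries, as were 26.4% of tested genes from 1 to 3 CPM in control. Ntn1, which encodes netrin 1, had a log2 fold change of -1.67 (SE 0.17). Col1a2, which encodes the other chain of type I collagen, had 0.31 (SE 0.08), opposite in sign to Col1a1. The collagen and matrix list held 18 of 24 members lower (camera adjusted p = 0.0818, 0.414 with an estimated correlation, fry adjusted p = 0.00747). Over the list alone 10 lower members passed, among them Col6a1 at a log2 fold change of -2.86 (SE 0.28) and Fn1, fibronectin, at -0.79 (SE 0.15). The 4 higher members that passed were the laminin chains Lama5 (1.26, SE 0.12), Lamb1 (0.59, SE 0.08) and Lamc1 (0.39, SE 0.09), and Col1a2. The collagen and matrix call appeared without Brg1-cKO replicate 1 (adjusted p = 2.78e-04) and without replicate 2 (0.00963).

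Endothelial genes were lower as a set (14 of 16, camera adjusted p = 0.00888, 0.418 with an estimated correlation, fry adjusted p = 0.117), with 0 past the threshold over the list alone. Pecam1 was at 28.6 ± 11.7 CPM in Brg1-cKO against 87.4 ± 7.17 CPM in control, while Cldn5, a claudin of tight junctions, had a log2 fold change of 1.11 (SE 0.22). Immune genes were lower as a set (14 of 15, camera adjusted p = 0.00589, 0.411 with an estimated correlation, fry adjusted p = 0.0264), also with 0 past the threshold over the list alone. C1qa, a complement gene of macrophages, was at 9.41 ± 0.650 CPM in control and at 0 counts in both Brg1-cKO libraries. In the Brg1-cKO libraries 1527 tested genes were at 0 in both, against 52 in the controls, and scarce markers of any cell type are affected by this.

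Mitochondrially encoded genes were higher as a set (14 of 18, camera adjusted p = 3.93e-04, 0.411 with an estimated correlation, fry adjusted p = 0.117), and 8 passed over the list alone. They took 3.21% ± 0.279 of counts in Brg1-cKO and 2.37% ± 0.115 in control. Ribosomal protein genes took 2.78% ± 0.0447 and 2.99% ± 0.0667, with 31 of 86 higher (camera adjusted p = 0.988). In the list of dissociation and immediate early genes 13 of 17 were lower (camera adjusted p = 0.149), and Egr1, Fosb and Jun passed over the list alone, the latter 2 at log2 fold changes of -0.51 (SE 0.07) and -0.40 (SE 0.07). With an estimated correlation this list's camera adjusted p was 0.716. It was called without Brg1-cKO replicate 1, in a fit that left a single Brg1-cKO library. Cdkn1c, which encodes the cell cycle inhibitor p57, was the only member of the CDK inhibitor list past the threshold over the list (log2 fold change 0.70, SE 0.08), where 3 of 6 were higher (camera adjusted p = 0.570). In the FGF response list 7 of 14 were higher (camera adjusted p = 0.644) and Fgf9, a ligand made by nephron progenitors, passed over the list alone (2.90, SE 0.37).

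Cell cycle lists showed no set change, with 8 of 22 S phase genes higher (camera adjusted p = 0.988) and 10 of 22 G2 and M phase genes higher (adjusted p = 0.340). The p53 and apoptosis list had 10 of 20 higher (adjusted p = 0.788), posterior Hox genes 7 of 13 (0.988), BMP and TGF-beta response genes 8 of 15 (0.988), and glycolysis and hypoxia genes 5 of 21 (0.406). In none of these 6 lists did a member pass over the list alone. Muscle genes were higher in 4 of 8 (adjusted p = 0.988), also with 0 past the threshold over the list. Of the erythroid list 3 of 5 tested members were higher (0.988), and Epb42 passed over the list alone, at 0 counts in Brg1-cKO and 0.704 ± 0.151 CPM in control. Of the neuron and glia list 7 of 14 were higher (0.988, and 0.0207 with a filter of 10 CPM in 2 libraries). In that list 1 member passed over the list alone as higher and 3 as lower, the latter Fabp7, Chga and Stmn2, all at 0 counts in Brg1-cKO. For the Six-Eya-Dach-Pbx, Myc, S phase, G2 and M phase, Notch, neuron and ribosomal protein lists camera pointed up while the median was below 0, and for the erythroid list it pointed down while the median was 1.84. For the muscle, p53, Hox and BMP lists the median was above 0 and the mean below.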

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

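The tests in this part were chosen after the results were seen, except the test for shared silent genes, which was fixed before its value was computed.

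Reads given to no gene were above both controls in each Brg1-cKO library. Reads that matched no counted feature made up 49.5% and 57.2% of uniquely aligned reads in Brg1-cKO replicates 1 and 2, against 16.5% and 15.4% in the controls. Unaligned reads made up 21.3% and 25.5% of all reads, against 6.32% and 6.69%.

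Genes that are normally silent in kidney also took more counts in Brg1-cKO, with olfactory receptor genes at 769 ± 472 CPM against 56.6 ± 16.1 CPM in control, on 124 ± 42.4 detected genes against 194 ± 12.7. Olfactory receptor CPM in the lower Brg1-cKO library was 6.40 times that in the higher control, which restates the pattern. These genes held only 435 and 1103 CPM in Brg1-cKO replicates 1 and 2, so the ratio does not bear on the reads outside genes. Unspliced RNA in introns stays open as a source of those reads. Few starting molecules, each read many times, may contribute, as genes detected with gene counts thinned to the same total were 0.704 of control and each detected olfactory receptor gene held 73.0 ± 7.39 counts against 10.6 ± 1.82. Genomic DNA stays open, because the number of these genes detected, 0.113 of what independent and evenly spread reads would give in the higher library, would also be low if a few DNA fragments had been read many times. A biological alternative, transcription of the same silent genes after loss of Brg1, stays open, with 92 genes at 0 in both controls detected in both Brg1-cKO libraries, 3.59 times the number matched on exon length, while olfactory receptor genes shared between libraries exceeded chance by 2.34 times in control and 2.52 times in Brg1-cKO, a comparison added after the first value was seen.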

How the results depend on the processing

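The alternatives that use a variance per group, no robust dispersion, a filter of 10 CPM or thinned counts were chosen after seeing the data. The count of 0 genes was the same with RLE, total counts, no filter, 1 CPM, 10 CPM, thinned counts, no robust dispersion, glmTreat, an adjusted p of 0.01 and without mitochondrial, ribosomal protein and hemoglobin genes. Genes changed, higher and lower numbered 2027, 1249 and 778 with DESeq2, 2471, 551 and 1920 with the likelihood ratio test, 327, 61 and 266 with limma-voom, and 134, 105 and 29 with limma-voom and a variance per group. With libraries left out in turn they ranged from 13 to 13134, from 11 to 4978 and from 2 to 8238, the upper ends without a Brg1-cKO library. The median log2 fold change of all tested genes moved from -0.06 to -0.28 with DESeq2 and -0.61 in edgeR without a filter, both on 30930 genes, and to -0.31 with the replicate block and with limma-voom. In the simulation limma-voom made 2 calls, neither of them false, and limma-voom with a variance per group 133, of which 66 were false. Low detection and spread in the Brg1-cKO libraries limit what the counts can show for scarce genes. At 0 in both were 23.3% of genes under 1 CPM in control, 26.4% of those from 1 to 3 CPM and 5.98% of those from 3 to 10 CPM. Depth alone does not account for this, as genes detected with gene counts thinned to the smallest total were 0.704 of control.

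With the replicate block 156 genes passed, 112 higher and 44 lower, and in the simulation it made 93 calls, of which 14 were false. Nothing says that the numbers pair the libraries, the deviations of same-numbered libraries correlated at -0.02, and with 2 pairs this cannot be settled. The block ended the Wnt list's call and kept the other 9.

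Smarca4 kept its direction in every alternative. Its model-based single-gene p, for which 2 against 2 libraries allow no useful exact test, missed 0.05 at a log2 fold change of -0.34 with the likelihood ratio test (p = 0.102) and glmTreat (p = 0.873) and of -0.33 with a variance per group (p = 0.0723). With libraries left out it ranged from -0.41 to -0.27. Of named genes, Eya1 turned to 0.0426 with DESeq2, 0.0424 with RLE, 0.00013 at 1 CPM, 0.0129 at 10 CPM and 0.0306 when thinned, and ranged from -0.29 to 0.22 with libraries left out. Cited1 turned to -0.20 with the block and ranged from -1.63 to 1.21. Lin28b ranged from -1.55 to 0.0246. The cause was not tested. Across the named genes reported and the alternatives 294 values kept direction and side of the threshold, 105 gained a call, 5 lost one and 10 turned.

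Of the 28 lists 10 were called, 0 with an estimated correlation, 5 with fry (4 of the 10, and collagen), 11 at 10 CPM (8 of the 10) and 10 when thinned (9 of the 10). At 10 CPM the nephron progenitor (adjusted p = 0.0604) and SWI/SNF (0.0820) lists lost their call, and neuron and glia (0.0207), dissociation (0.0147) and collagen (0.00175) gained one. When thinned, Wnt (0.0635) lost its call and collagen (0.0424) gained one. RLE kept all 10, as did leaving out either control, while 8 stayed without Brg1-cKO replicate 1 and 9 without replicate 2. Of the lists that were not called, tubule, G2 and M phase, CDK inhibitors, dissociation, collagen and glycolysis kept their direction in each of these alternatives, and the others turned at these adjusted p-values. With fry they were 0.206 (Six-Eya, muscle, ribosomal), 0.607 (Myc), 0.194 (neuron, Hox), 0.414 (p53), 0.387 (S phase), 0.721 (FGF), 0.301 (BMP) and 0.897 (Notch). With RLE it was 0.993 (neuron, muscle). At 10 CPM they were 0.551 (Six-Eya), 0.951 (Myc), 0.663 (S phase), 0.855 (FGF) and 0.571 (ribosomal). When thinned they were 0.715 (Six-Eya) and 0.886 (muscle). With libraries left out the adjusted p ranged from 0.399 to 0.993 (Six-Eya), 0.580 to 0.984 (Myc), 0.576 to 0.9997 (erythroid), 0.560 to 0.989 (neuron), 0.971 to 0.9997 (muscle), 0.699 to 0.819 (p53), 0.616 to 0.979 (S phase), 0.680 to 0.984 (Hox), 0.533 to 0.709 (FGF), 0.580 to 0.993 (BMP), 0.595 to 0.954 (Notch) and 0.533 to 0.993 (ribosomal).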

Other observations

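All genes and tests in this part were chosen after their values were seen, except the test on X-linked genes that escape inactivation, which was fixed after the Xist pattern was seen and before its own value was computed.

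Beyond the fixed lists, the genes that follow were picked from those with the smallest p, none past an adjusted p of 0.05 over all genes in edgeR's quasi-likelihood test. Bcam, a laminin receptor, was at 429.9 ± 1.82 CPM in Brg1-cKO against 203.5 ± 7.35 CPM in control (log2 fold change 1.08, SE 0.10). Tgfbr3 had a log2 fold change of 1.87 (SE 0.20), Ddn, which encodes dendrin of the slit diaphragm, 3.11 (SE 0.32), and Crb2, a polarity protein of podocytes, 1.87 (SE 0.23). Cd274, which encodes the immune ligand PD-L1, was at 41.4 ± 7.35 CPM against 1.46 ± 0.115 CPM (log2 fold change 4.82, SE 0.50). Among lower genes stood Tbx2, a transcription factor of the mesenchyme, at -1.66 (SE 0.19), Pcdh17, a protocadherin, at -3.60 (SE 0.36), Prickle1, of planar cell polarity, at -2.90 (SE 0.34), and Dchs1, the ligand of the stromal cadherin Fat4, at -1.03 (SE 0.13). Mmp2, a matrix metalloproteinase, was at 94.0 ± 3.46 CPM against 204.5 ± 0.699 CPM (log2 fold change -1.12, SE 0.14). Bcam, Ddn, Crb2, Cd274, Dchs1 and Xist overlap an antisense gene (Tsix and others for Xist), and Tgfbr3 and Xist a gene on their own strand. The strand setting was not given, so it is not known which reads in the parts shared with antisense genes were counted.

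The podocyte list stood higher, and the stromal and ureteric bud lists lower, in Brg1-cKO. Control CPM did not account for these shifts. The podocyte median lay at percentile 100 of 10000 random lists matched on control CPM, and the stromal and ureteric bud medians at percentile 0. The lists were picked for having moved against other genes, and random members were drawn independently. The percentiles are therefore no separate test of loss of transcripts from libraries with few molecules. A trend with GC content or transcript length was argued against, since removing it left the medians near their values. These were 1.85 for podocyte, -1.05 for stroma and -1.87 for ureteric bud. The median residual was 1.86 (bootstrap 95% interval 1.63 to 2.76) for podocyte, -1.02 (-1.19 to -0.29) for stroma and -1.68 (-5.20 to -0.82) for ureteric bud. The intervals resample members of lists picked for having moved. They do not measure the spread between libraries and do not test the shifts themselves. Fewer stromal cells among the sorted cells cannot be told apart from lower expression within them, as of 14 stromal markers at 50 CPM or more in control 7 lay more than 2 SE below 0 and 2 more than 2 SE above, Col1a2 and Cspg4. A change of podocyte genes within cells after Brg1 loss, a larger share of podocytes in the sort and a difference in the age of the kidneys stay open and were not tested. The same holds for a smaller share of ureteric bud, endothelial or immune cells in the sort.

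Xist, the RNA of the inactive X chromosome, was at 836 and 1205 CPM in the Brg1-cKO libraries against 244 and 217 CPM in control, and the Y-linked Ddx3y was at 1.05 and 3.27 against 76.0 and 78.8 CPM. Genes matched on control CPM did not share this fall. The median log2 fold change of Ddx3y, Eif2s3y, Kdm5d and Uty, -4.75, lay at percentile 0 of matched random lists, though these genes were picked after the pattern was seen. All 4 Y-linked genes were lower in both Brg1-cKO libraries than in both controls, and Xist was higher. A larger share of female cells in Brg1-cKO would give this pattern, but the sex of the mice was not given in the sources used here. The median log2 fold change of Ddx3x, Eif2s3x, Kdm5c and Kdm6a, X-linked genes that escape inactivation, was 0.17, at percentile 87.7 of matched random lists, with Eif2s3x and Kdm5c higher and Ddx3x and Kdm6a lower. These 4 genes decide neither way, as they split in direction, and they do not count against the Xist and Y-linked pattern. No fit separated sex from genotype, so the group differences given here can include differences of sex.

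Predicted or clone-named genes were among the strongest higher values. Gm10800 was at 810.1 and 987 CPM in Brg1-cKO against 36.8 and 26.6 CPM in control, and Gm21738 at 112 and 98.8 CPM against 5.62 and 4.02 CPM. Such names made up 23.7% of genes higher at an unadjusted p under 0.05, 33% of the lower ones and 20.4% of all tested genes.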
